A study of Mus musculus with 14 samples.

How the data were processed

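The data were gene expression values of 14 whole ear samples, 3 or 4 in each of 4 groups of genotype and treatment. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq Stranded mRNA kit, and ears were taken 6 h after 20 µl of vehicle or of 1% croton oil. The submitters' processing notes name cutadapt, HISAT2, Subread and featureCounts and the mouse build mm10, without versions or order. The values were TPM as deposited by the authors, 1 value for each gene and sample, and each sample summed to 1e+06 over 24062 rows. How the TPM were computed from read counts, which annotation was used and whether reads were counted by strand are not given in the sources used here. TPM keep no depth, so sampling error could not be separated from other variation, and no counting intervals are given. A gene that takes a large share of a sample lowers the TPM of all others. The 10 most abundant genes held 7.20 to 10.1% of the TPM of a sample. Copies of a gene that share reads, such as the stefin, Serpina3 and Oas1 families, and overlapping genes were treated as uncertain.

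Samples were grouped by the labels, and 0 sample columns were left without a sample. Of the 24062 rows, 27 were named as dates and so named no gene. They held 0.124 to 0.145% of the TPM and were left out, leaving 24035 rows. No mitochondrial genes were listed. Of the 14693 genes tested, each had at least 1 TPM in at least 3 samples, and 9342 genes fell below this filter. The deposited values were transformed to log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 as 1 model with 4 group means over all 14 samples, with a mean-variance trend. The 5 comparisons were croton oil against vehicle in each genotype, LC-DTA against LC-DTR under each treatment, and the difference of the responses. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Values per group are given as mean ± SD in TPM. Files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

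Gene lists of cell types and pathways, 34 in number with 501 entries, were fixed before the data were examined, as were the groups, tests, filter, rule for named genes and alternatives. Of these, 493 entries were found among the deposited genes, 7 of them under an older symbol. The 31 lists with at least 3 tested genes were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. None of the camera calls held when the correlation was estimated for each list, and those p-values are given beside the calls. Fry was the other alternative, which tests whether the genes of a list move in 1 direction and compares them with no other genes. Gene positions are those of GENCODE M21 on GRCm38, and that annotation was not stated to be the one behind the values.

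Genes were named by a rule. For each comparison of 2 groups it took the 12 genes with the largest positive and the 12 with the largest negative log2 difference, among those called, with a mean of at least 5 TPM in 1 of the groups and no overlap between the groups. Predicted genes, Rik clones and ribosomal pseudogenes were passed over. For the difference of responses it took the 5 genes with the lowest p in each direction, and for each list described up to 4 members with the lowest p. Cd207, Mrgprd, Mrgprb2, Cpa3, Cma1, Mcpt4, Tpsb2 and Kit were always included. The text may use fewer genes than the rule allows, taken in order, and some results are not reported here. List members that moved against their list, and C1qa and C1qc, were named after their values were seen.

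The gene test was tested on simulated data, with 200 genes changed among 14693, 50 at each fold. For croton oil in LC-DTR it recovered 10 of 50 genes at 1.25-fold, 41 at 1.5-fold, 46 at 2-fold and 50 at 4-fold, with 16 false among 163 calls. For croton oil in LC-DTA it recovered 13, 33, 46 and 50, with 1 false call among 143. For the genotypes under vehicle it recovered 13, 25, 44 and 48, with 8 false among 138, and for the genotypes after croton oil 15, 32, 46 and 49, with 5 false among 147. For the difference of responses it recovered 2, 26, 34 and 50, with 7 false among 119. On the same data camera called 0 lists without change and called the changed list of 20 genes in each comparison. The simulated genes varied independently of each other, so this does not show how camera behaves with correlated genes.

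The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, rescaling by the median ratio and quantile normalization, limma without the trend and with robust estimation, the replicate number as a block, only the compared groups in the fit, leaving out LC-DTA croton oil samples 3 and 4 together, whose label numbers lie apart from those of samples 1 and 2, and leaving out each sample in turn.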

Results

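The series measured gene expression by mRNA sequencing in whole mouse ear tissue, which holds epidermis, dermis, cartilage and the cells resident in them. In both genotypes Langerhans cells, the dendritic cells of the epidermis, had been removed. In LC-DTA mice they were missing long term, and in LC-DTR mice they had been ablated by diphtheria toxin (DT) 3 days earlier. Ears were painted on both sides with 20 µl of vehicle, a mixture of acetone and olive oil at 4 to 1, or of 1% croton oil in vehicle, and taken after 6 h. Croton oil is a skin irritant that holds phorbol esters, which activate protein kinase C. There were 3 LC-DTR vehicle, 4 LC-DTR croton oil, 3 LC-DTA vehicle and 4 LC-DTA croton oil samples, and no sample with intact Langerhans cells was analysed here. The title of the series names mast cell homeostasis. The comparison of the genotypes under vehicle addressed skin without the irritant, and the croton oil groups addressed acute irritation. No unpainted ears were among the samples. Expression was given in TPM, a unit that divides by the total of each sample and keeps no record of how many reads were sequenced, so the depth of each sample was unknown. Each sample had between 13753 and 14353 genes at 1 TPM or more. The labels did not say that samples of a group came from separate animals, so p-values measured only the spread between these samples. All TPM values below are mean ± SD over 3 vehicle or 4 croton oil samples, and all log2 differences are on the log2(TPM + 1) scale ± SE, which understates the change of genes with low TPM.

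The samples separated by treatment along the first principal component, which held 50.5% of the variance, and by genotype along the second, with 27.6%. LC-DTR croton oil samples 2 and 3 lay at 5.26 and 8.06 on the first component and samples 1 and 4 of that group at 28.5 and 28.6. Within groups the correlation of log2 values across genes was 0.994 to 0.998, and no pair of libraries was identical. Xist was between 64.7 and 108 TPM in every sample, and the Y-linked genes measured stayed at or below 0.137 TPM. Cd207, which encodes langerin, the marker of Langerhans cells and of some dermal dendritic cells, lay on chromosome 6 from 83671215 to 83677857 (all coordinates are GRCm38, the build named mm10). It was near the lower end of the scale in each group, at 0.259 ± 0.192 TPM in LC-DTR vehicle, 1.18 ± 0.687 in LC-DTR croton oil, 0.290 ± 0.320 in LC-DTA vehicle and 0.529 ± 0.137 in LC-DTA croton oil samples. Cd207 did not pass the expression filter, and without the filter limma called it higher after croton oil in LC-DTR, by 0.74 ± 0.23 (adjusted p = 0.0222), and in none of the other comparisons. Mrgprd, the receptor that names the sensory neurons in the title of the series, was at 0.0706 TPM or below in every sample. The cell bodies of sensory neurons lie outside the ear, so ear mRNA says little about them.

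**Figure D1:**
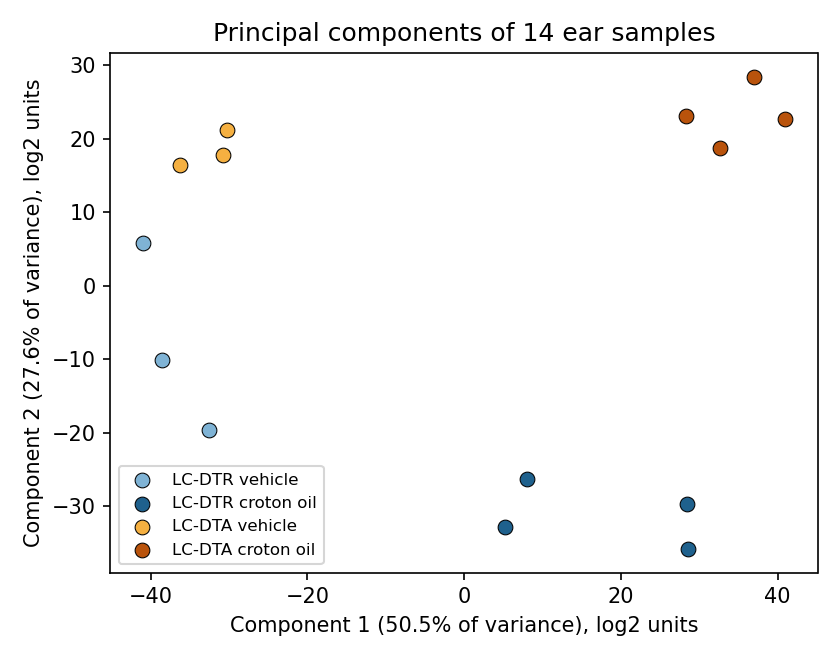
First against second principal component of log2(TPM + 1) over the genes tested, in log2 units, with 1 point for each of the 14 ear samples, coloured by genotype and treatment. The croton oil samples lie to the right of the vehicle samples along component 1 (50.5% of the variance), and the LC-DTA samples lie above the LC-DTR samples along component 2 (27.6%).

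The first comparison asked how ears with short-term loss of Langerhans cells responded to croton oil. In LC-DTR ears, croton oil was followed by higher expression of keratinocyte stress genes, phorbol ester targets, neutrophil genes and the cytokines and chemokines that attract neutrophils, and by lower expression of cell cycle and hair follicle genes. Cxcl1, a chemokine that attracts neutrophils (chromosome 5, 90891241 to 90893115), rose from 26.5 ± 21.8 to 308 ± 65.2 TPM, and S100a8, which encodes a subunit of calprotectin, rose from 11.99 ± 6.67 to 185 ± 96.1 TPM. Mcm2, which encodes a subunit of the replicative helicase (chromosome 6, 88883474 to 88898780), fell from 19.1 ± 2.64 to 4.60 ± 0.639 TPM. The protease genes of mast cells did not differ detectably. The LC-DTR croton oil samples had consecutive label numbers, 10851 to 10854, and the LC-DTR vehicle samples had 10825, 10968 and 11098. A difference between sets of samples that follows these numbers was not tested.

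Of 14693 genes tested, limma called 7577 at an adjusted p under 0.05 in LC-DTR, 3243 higher and 4334 lower after croton oil, and of these 534 were higher and 323 lower by at least 2-fold. The share called higher depended on the scaling. It was 42.8% as deposited, 49.8% after median ratio scaling (3784 higher and 3809 lower) and 45.1% after quantile normalization (3373 higher and 4112 lower). The increases with the largest log2 values were those of Sh2d5 (chromosome 4, 138250403 to 138261332) at 4.34 ± 0.32, Cxcl1 at 4.05 ± 0.56, Retnlg, a secreted protein of neutrophils, at 4.03 ± 0.30, S100a8 at 3.84 ± 0.48, the beta-defensin Defb3 at 3.78 ± 0.28 and the chemokine Ccl20 at 3.57 ± 0.80, with limma adjusted p between 9.02e-07 and 0.00213. The largest decreases were those of Sostdc1, a secreted antagonist of BMP and Wnt signalling (chromosome 12, 36314139 to 36318452), at -3.09 ± 0.22, Cyp2w1 at -2.60 ± 0.24, Hs3st6 at -2.60 ± 0.27, the p53 family member Trp73 at -2.48 ± 0.33, the potassium channel gene Kcnj16 at -2.31 ± 0.21 and the Myc family member Mycl at -2.11 ± 0.26. Their limma adjusted p lay between 8.03e-07 and 5.57e-05.

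Among the gene lists, 21 of 23 measured keratinocyte stress and antimicrobial genes rose in LC-DTR, none fell and 2 were not called (21 higher when adjusted over the list alone). Il1f6, an interleukin-36 cytokine, was higher by 1.15 ± 0.083 and Krt6a, a keratin of wounded epidermis, by 1.97 ± 0.15. The list's camera adjusted p was 3.60e-11, and it had adjusted p = 0.290 with an estimated correlation. Of 19 phorbol ester and AP-1 targets 18 rose (18 adjusted over the list alone), among them the MAP kinase phosphatase Dusp5 at 1.57 ± 0.12 and the urokinase receptor Plaur at 2.24 ± 0.18. Camera gave the phorbol ester and AP-1 list adjusted p = 3.60e-11, and adjusted p = 0.290 with an estimated correlation. Of 19 neutrophil genes 17 rose (17 adjusted over the list alone), with Retnlg and the G-CSF receptor Csf3r, at 2.26 ± 0.21, as examples. Camera gave the neutrophil list adjusted p = 2.25e-09, and adjusted p = 0.290 with an estimated correlation. Of 15 neutrophil-attracting chemokines and growth factors 14 rose (14 adjusted over the list alone), with Il6 at 2.94 ± 0.24 and Osm at 1.93 ± 0.17. Camera gave the neutrophil-attracting chemokine list adjusted p = 7.01e-08, and adjusted p = 0.290 with an estimated correlation.

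Immediate early genes rose in LC-DTR as well, 13 of 15 (13 adjusted over the list alone), with Btg2 at 1.27 ± 0.11 and Ier3 at 1.70 ± 0.16. Camera gave the immediate early list adjusted p = 2.86e-06, and adjusted p = 0.388 with an estimated correlation. Of 15 genes of NF-kB feedback 12 rose and 1, the interleukin-1 receptor antagonist Il1rn, fell, the same counts when adjusted over the list alone, with Bcl3 at 2.95 ± 0.26 and Tnfaip2 at 1.53 ± 0.15. Camera gave the NF-kB feedback list adjusted p = 1.52e-05, and adjusted p = 0.312 with an estimated correlation. Of 11 endothelial activation genes 7 rose (7 adjusted over the list alone), among them the protease Adamts4 at 2.98 ± 0.17 and Sele, which encodes E-selectin, at 2.27 ± 0.25. Camera gave the endothelial activation list adjusted p = 4.17e-04, and adjusted p = 0.290 with an estimated correlation. Of 19 monocyte and lymphocyte chemokines 10 rose and 2, Ccl22 and Cx3cl1, fell (11 and 2 adjusted over the list alone), with Ccl7 at 3.23 ± 0.25 and Ccl3 at 2.35 ± 0.21. Camera gave the monocyte and lymphocyte chemokine list adjusted p = 9.80e-04, and adjusted p = 0.312 with an estimated correlation. Of 10 heat shock genes 6 rose (6 adjusted over the list alone), with the co-chaperones Bag3 at 0.60 ± 0.059 and Dnajb1 at 0.52 ± 0.065. Camera gave the heat shock list adjusted p = 0.00653, and adjusted p = 0.388 with an estimated correlation.

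The type 2 cytokine and alarmin genes went both ways in LC-DTR, with 5 of 9 higher and 1 lower, the same counts when adjusted over the list alone. The receptor Il4ra rose by 1.70 ± 0.17, the TSLP receptor Crlf2 by 0.60 ± 0.075 and the EGF receptor ligand Areg by 2.05 ± 0.27, whereas the alarmin Il33 fell, at -1.34 ± 0.21. Camera gave the type 2 cytokine list adjusted p = 0.00651, and adjusted p = 0.312 with an estimated correlation. Of 15 cell cycle genes 13 fell and 1, the ribonucleotide reductase gene Rrm2, rose, the same counts when adjusted over the list alone, with Mcm2 at -1.85 ± 0.11, Mcm5 at -1.86 ± 0.14 and the proliferation marker Mki67 at -1.49 ± 0.22. Camera gave the cell cycle list adjusted p = 4.09e-04, and adjusted p = 0.547 with an estimated correlation. Beside this, of 17 epidermal genes 9 fell and 2 rose, the same counts when adjusted over the list alone, with a median of -0.36. Camera did not call the epidermal list (adjusted p = 0.254, and adjusted p = 0.638 with an estimated correlation), and fry did, at adjusted p = 6.45e-04. Of 10 hair follicle genes 5 fell (5 adjusted over the list alone), with the root sheath keratin Krt28 at -1.003 ± 0.15 and Msx2 at -0.79 ± 0.13. Camera gave the hair follicle list adjusted p = 0.0435, and adjusted p = 0.388 with an estimated correlation. The circadian and glucocorticoid list was not called, with 6 of 16 higher and 4 lower, the same counts when adjusted over the list alone. The clock output gene Dbp fell, at -1.81 ± 0.15, and Per3 fell, at -1.42 ± 0.13, while Fkbp5, a co-chaperone gene that glucocorticoids induce, rose by 1.94 ± 0.22. Camera gave the circadian and glucocorticoid list adjusted p = 0.681, and adjusted p = 0.946 with an estimated correlation.

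Of 20 mast cell genes in LC-DTR 6 rose, 2, Ms4a2 and Rab27b, fell and 12 were not called (5 higher and 2 lower adjusted over the list alone). Camera gave the mast cell list adjusted p = 0.350, and adjusted p = 0.946 with an estimated correlation. Hdc, which encodes the enzyme that makes histamine and is also expressed in neutrophils, rose by 2.26 ± 0.20 (limma adjusted p = 3.24e-06). The log2 difference of Cpa3 was -0.12 ± 0.18, that of Cma1 -0.084 ± 0.18, that of Mcpt4 -0.28 ± 0.22 and that of Tpsb2 0.078 ± 0.17, and the receptor genes Kit and Mrgprb2 differed by -0.29 ± 0.14 and -0.14 ± 0.17. The limma adjusted p of these genes, none of them called, lay between 0.0959 and 0.729. Kit was called lower, at -0.40, without LC-DTR vehicle sample 2. The hair follicle call was lost, at camera adjusted p from 0.0544 to 0.128, without LC-DTR vehicle sample 3, without LC-DTR croton oil sample 2 or 3, with pseudocount 5 and with a filter of 5 TPM.

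**Figure D2:**
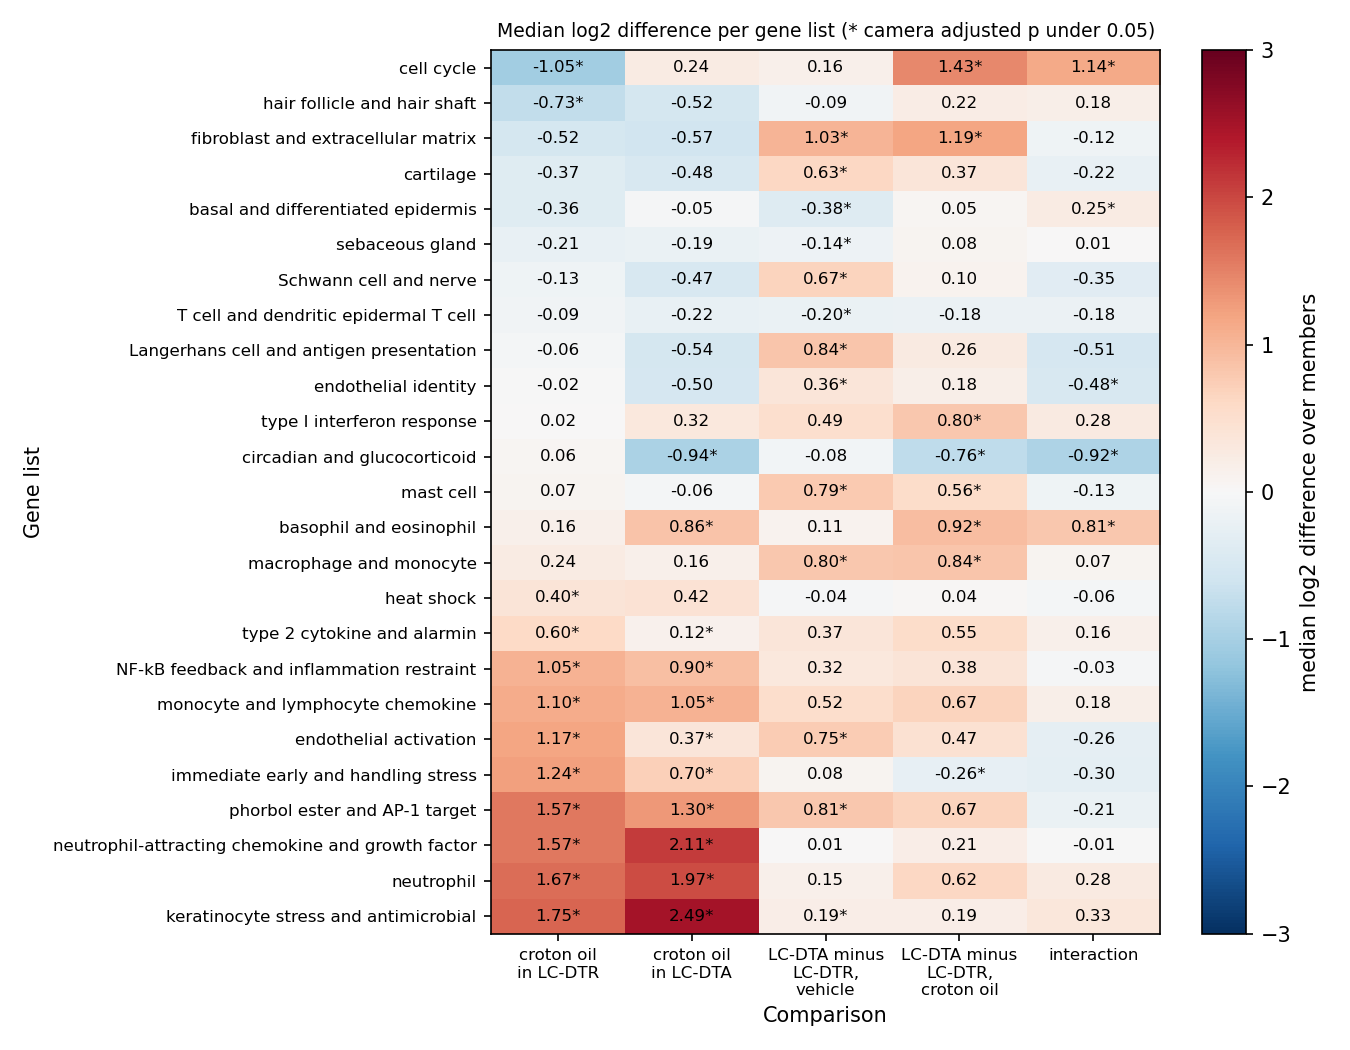
Median log2 difference over the measured members of each of the 25 gene lists called by camera in at least 1 comparison (vertical axis), for each of the 5 comparisons (horizontal axis); the colour and the printed value give the median, and a star marks a camera adjusted p under 0.05. Keratinocyte stress genes have medians of 1.75 and 2.49 after croton oil, and cell cycle genes have -1.05 in LC-DTR and 0.24 in LC-DTA.

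The second comparison asked the same of ears with long-term loss of Langerhans cells. In LC-DTA ears croton oil was followed by higher expression of the keratinocyte stress, neutrophil, chemokine and phorbol ester lists, of stefin genes of neutrophils and of Ccr3, Mcpt8 and Cd200r3, genes of basophils and eosinophils. Genes of the circadian clock and of the glucocorticoid response fell. Of this list the clock genes Dbp, Hlf, Per3 and Tef had fallen in LC-DTR as well, while others of the list rose there. Stfa3, a cysteine protease inhibitor (chromosome 16, 36450537 to 36455392), rose from 7.50 ± 1.91 to 269 ± 54.3 TPM, and Ch25h, which encodes cholesterol 25-hydroxylase, from 2.03 ± 0.244 to 67.1 ± 5.06 TPM. Sostdc1 fell from 44.3 ± 3.26 to 5.85 ± 1.75 TPM.

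In LC-DTA limma called 8619 genes, 3552 higher and 5067 lower after croton oil, and of these 548 were higher and 454 lower by at least 2-fold. Here too the share called higher depended on the scaling. It was 41.2% as deposited, 48.2% after median ratio scaling (4138 higher and 4455 lower) and 46.4% after quantile normalization (3995 higher and 4624 lower). The increases with the largest log2 values were those of BC100530 at 5.54 ± 0.73, Stfa3 at 4.99 ± 0.46, the cytokine Il19 at 4.86 ± 0.62, Stfa1 at 4.85 ± 0.46, Ccl20 at 4.80 ± 0.80, Stfa2 at 4.64 ± 0.55 and Ch25h at 4.49 ± 0.23, with limma adjusted p between 1.48e-07 and 1.90e-04. BC100530, Stfa1, Stfa2 and Stfa3 are near-identical copies whose shared reads could be split between them, so their single values are uncertain. The largest decreases were those of Sostdc1 at -2.75 ± 0.22, Tppp at -2.64 ± 0.26, the noradrenaline transporter gene Slc6a2 at -2.62 ± 0.23, Mycl at -2.53 ± 0.26, the transcription factor gene Rfx2 at -2.499 ± 0.25 and the homeobox gene Irx4 at -2.21 ± 0.19. Their limma adjusted p lay between 1.07e-06 and 4.85e-06.

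Of 23 keratinocyte stress genes 22 rose in LC-DTA (22 adjusted over the list alone), with Il1f6 at 1.49 ± 0.083 and Krt6a at 2.30 ± 0.15. Camera gave the keratinocyte stress list adjusted p = 3.48e-12, and adjusted p = 0.274 with an estimated correlation. Of 19 neutrophil genes 17 rose and 1, the decoy receptor Il1r2, fell, the same counts when adjusted over the list alone, with Cd177 at 1.89 ± 0.11. Camera gave the neutrophil list adjusted p = 1.60e-09, and adjusted p = 0.274 with an estimated correlation. Of 19 phorbol ester and AP-1 targets 17 rose (17 adjusted over the list alone), with the phosphatase Dusp6 at 2.45 ± 0.20 and the stromelysin Mmp3 at 1.80 ± 0.16. Camera gave the phorbol ester and AP-1 list adjusted p = 1.60e-09, and adjusted p = 0.274 with an estimated correlation. Of 15 neutrophil-attracting chemokines and growth factors 14 rose (14 adjusted over the list alone), with Il6 at 3.98 ± 0.24, Osm at 2.66 ± 0.17 and Cxcl5 at 3.57 ± 0.24. Camera gave the neutrophil-attracting chemokine list adjusted p = 3.96e-08, and adjusted p = 0.274 with an estimated correlation.

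Of 15 genes of NF-kB feedback 12 rose in LC-DTA (12 adjusted over the list alone), with Bcl3 at 2.82 ± 0.26 and Il10 at 2.23 ± 0.24. Camera gave the NF-kB feedback list adjusted p = 1.83e-05, and adjusted p = 0.307 with an estimated correlation. Of 19 monocyte and lymphocyte chemokines 10 rose and 3, Ccl22, Ccl27a and Cx3cl1, fell, the same counts when adjusted over the list alone, with Ccl7 at 3.70 ± 0.25 and Ccl12 at 3.92 ± 0.36. Camera gave the monocyte and lymphocyte chemokine list adjusted p = 0.00136, and adjusted p = 0.307 with an estimated correlation. Immediate early genes went both ways, 10 of 15 higher and 2 lower (the same counts when adjusted over the list alone). Ier3 rose, at 1.54 ± 0.16, and the transcription factor genes Klf4, at -0.83 ± 0.089, and Fosb fell. Camera gave the immediate early list adjusted p = 0.00358, and adjusted p = 0.548 with an estimated correlation. Of 11 endothelial activation genes 5 rose (5 adjusted over the list alone), with Adamts4 at 2.99 ± 0.17 and Csf2rb at 1.41 ± 0.20. Camera gave the endothelial activation list adjusted p = 0.0162, and adjusted p = 0.307 with an estimated correlation.

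Of 8 genes of the basophil and eosinophil list 3 passed the filter, of which Ccr3 and Mcpt8 reached 1 TPM in 3 samples each and only in LC-DTA croton oil, and Cd200r3 in all 4 samples of that group and 2 of LC-DTA vehicle. The filter thus took in genes by their level in the group compared, and the number that rose (3, and 3 adjusted over the list alone) and the camera test of these genes are not independent of it. The eotaxin receptor gene Ccr3 went from 0.162 ± 0.0921 to 1.11 ± 0.213 TPM, the basophil protease gene Mcpt8 from 0.0525 ± 0.0910 to 1.32 ± 0.375 TPM and Cd200r3 from 1.05 ± 0.301 to 2.47 ± 0.282 TPM. These were low levels, and the list no longer had enough measured genes with a filter of 5 TPM or without LC-DTA croton oil sample 2, 3 or 4. Camera gave the 3 genes adjusted p = 0.00735, and adjusted p = 0.274 with an estimated correlation. Without the filter 4 of the 8 listed genes rose and none fell (4 adjusted over the list alone), the fourth being Siglec5, named after its values were seen, and camera gave adjusted p = 0.00765, and adjusted p = 0.195 with an estimated correlation. Of 9 type 2 cytokine and alarmin genes 4 rose (4 adjusted over the list alone), with Il4ra at 2.04 ± 0.17, Areg at 2.97 ± 0.27 and Il13 at 0.77 ± 0.11. Camera gave the type 2 cytokine list adjusted p = 0.0371, and adjusted p = 0.381 with an estimated correlation; the camera call was lost, at adjusted p from 0.0506 to 0.124, under both rescalings of the samples, with a filter of 5 TPM, with only the compared groups in the fit, without LC-DTA croton oil sample 3 and without samples 3 and 4 of that group. Of 16 circadian and glucocorticoid genes 14 fell (14 adjusted over the list alone), with Dbp at -2.03 ± 0.15, the nuclear receptor Nr1d1 at -1.24 ± 0.14 and Tef at -1.16 ± 0.13. Camera gave the circadian and glucocorticoid list adjusted p = 2.39e-04, and adjusted p = 0.307 with an estimated correlation.

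Of 15 cell cycle genes 6 rose in LC-DTA and 9 were not called (4 higher adjusted over the list alone), with Rrm2 at 1.49 ± 0.19, Pcna at 0.53 ± 0.084 and Mcm2 at 0.37 ± 0.11; camera did not call the list (adjusted p = 0.0686, and adjusted p = 0.726 with an estimated correlation). The call of Mcm2 was lost, at a log2 difference of 0.31, without LC-DTA vehicle sample 3 and, at 0.30, without LC-DTA croton oil samples 3 and 4. Of 16 macrophage and monocyte genes 7 rose and 6 fell (7 and 6 adjusted over the list alone). Among those that rose were Ccr2 at 2.52 ± 0.18 and Ly6c2 at 3.38 ± 0.35, genes of blood monocytes, and among those that fell were the complement genes C1qa and C1qc of tissue macrophages. Camera gave the macrophage and monocyte list adjusted p = 0.112, and adjusted p = 0.726 with an estimated correlation. Of 20 mast cell genes 7 rose and 5 fell, the latter Gata2, Kit, Mrgprb2, Ms4a2 and Tpsb2, the same counts when adjusted over the list alone. The interleukin-33 receptor gene Il1rl1 rose by 1.40 ± 0.18, whereas Tpsb2 at -0.69 ± 0.17, Kit at -0.73 ± 0.14 and Mrgprb2 at -0.91 ± 0.17 were lower after croton oil, with limma adjusted p between 5.07e-04 and 0.00360. Cpa3 at -0.44 ± 0.18, Cma1 at -0.24 ± 0.18 and Mcpt4 at -0.21 ± 0.22 were not called, with limma adjusted p between 0.0552 and 0.427; Cpa3 was called lower without LC-DTA vehicle sample 1, LC-DTA croton oil sample 2, LC-DTR vehicle sample 2 or LC-DTR croton oil sample 3 or 4, under quantile normalization and with only the compared groups in the fit, at log2 values from -0.60 to -0.44. For the mast cell list as a whole camera gave adjusted p = 0.506, and adjusted p = 0.856 with an estimated correlation.

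The third comparison set long-term against short-term loss of Langerhans cells in ears that had received vehicle only. In the lists of mast cells, fibroblasts, macrophages, endothelium and antigen presentation more genes were higher than lower in LC-DTA against LC-DTR ears, and 5 of 17 genes of basal and differentiated epidermis were lower. The mast cell proteases Cpa3 (chromosome 3, 20215620 to 20242181), Cma1 (chromosome 14, 55941451 to 55944675) and Mcpt4 (chromosome 14, 56059629 to 56062313) measured 99.2 ± 19.2, 148 ± 31.7 and 186 ± 43.2 TPM in LC-DTA and 51.7 ± 11.6, 68.1 ± 18.5 and 85.3 ± 16.6 TPM in LC-DTR. Mrgprb2, a receptor of connective tissue mast cells (chromosome 7, 48550965 to 48558086), measured 6.23 ± 0.738 TPM in LC-DTA and 2.93 ± 0.429 TPM in LC-DTR.

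Under vehicle limma called 3595 genes between the genotypes, 2810 higher and 785 lower in LC-DTA, and of these 176 were higher and 24 lower by at least 2-fold. The median of all genes tested was 0.097 above 0 on the log2 scale. Quantile normalization of the samples moved it by -0.11, to -0.014, and then 1616 genes were higher and 1772 lower, a share of 47.7% higher against 78.2% as deposited; after median ratio scaling 1900 were higher and 1430 lower, a share of 57.1%. Where it is stated, the list medians of this comparison are therefore given relative to the median gene. The count of 3595 was 1781 without LC-DTR vehicle sample 2 and 2093 without LC-DTA vehicle sample 3. The study's description gives DT administration for LC-DTR and does not say whether LC-DTA mice received it, and the numbers in the sample labels lie in separate ranges for the genotypes, so that neither can be told apart from genotype.

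The increases with the largest log2 values in LC-DTA under vehicle were those of Sptssb, a subunit of serine palmitoyltransferase, at 3.08 ± 0.501, the neurotensin precursor Nts (chromosome 10, 102481756 to 102490486) at 2.45 ± 0.22, Mmp3 at 2.25 ± 0.17, Tnfaip6 at 2.01 ± 0.27, Serpina3j at 2.001 ± 0.42, the collagen gene Col3a1 at 1.95 ± 0.46, Serpina3b at 1.88 ± 0.39 and Apold1 at 1.88 ± 0.18. Serpina3j and Serpina3b belong to a family of close copies, whose single values are uncertain. Relative to the median gene these differences were between 1.78 and 2.98, and their limma adjusted p lay between 2.09e-05 and 0.00818. Nts went from 2.68 ± 1.27 to 18.4 ± 1.94 TPM. The largest decreases were those of the Mas-related receptor gene Mrgprb3 (chromosome 7, 48642803 to 48643811) at -1.73 ± 0.27, the wax synthase Awat2 of sebaceous glands at -1.68 ± 0.35, Pctp at -1.49 ± 0.34, the beta-defensin Defb14 at -1.46 ± 0.25, Oas1e at -1.35 ± 0.23 and the fatty acid elongase Elovl6 at -1.30 ± 0.25. Relative to the median gene they were between -1.82 and -1.40, with limma adjusted p between 0.00111 and 0.00739.

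Of 20 mast cell genes 13 were higher in LC-DTA under vehicle, 1, Rab27b, was lower and 6 were not called (14 higher and 1 lower adjusted over the list alone), with a median of 0.69 relative to the median gene, a camera adjusted p of 3.84e-04, and adjusted p = 0.721 with an estimated correlation. The receptor gene Mrgprb1 was higher by 1.65 ± 0.19, Hdc by 1.54 ± 0.22, Cma1 by 1.12 ± 0.19, the transcription factor Gata2 by 0.86 ± 0.15, Mcpt4 by 1.10 ± 0.23, Cpa3 by 0.93 ± 0.20, Mrgprb2 by 0.88 ± 0.18 and Kit, the stem cell factor receptor, by 0.77 ± 0.15. Their limma adjusted p lay between 3.25e-04 and 0.00464. Tpsb2 was higher by 0.60 ± 0.19 (limma adjusted p = 0.0314), a call that was lost without LC-DTR vehicle sample 2 or 3, without LC-DTA vehicle sample 2 or 3, after median ratio scaling, without the filter and with only the compared groups in the fit, at log2 values from 0.47 to 0.60.

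**Figure D3:**
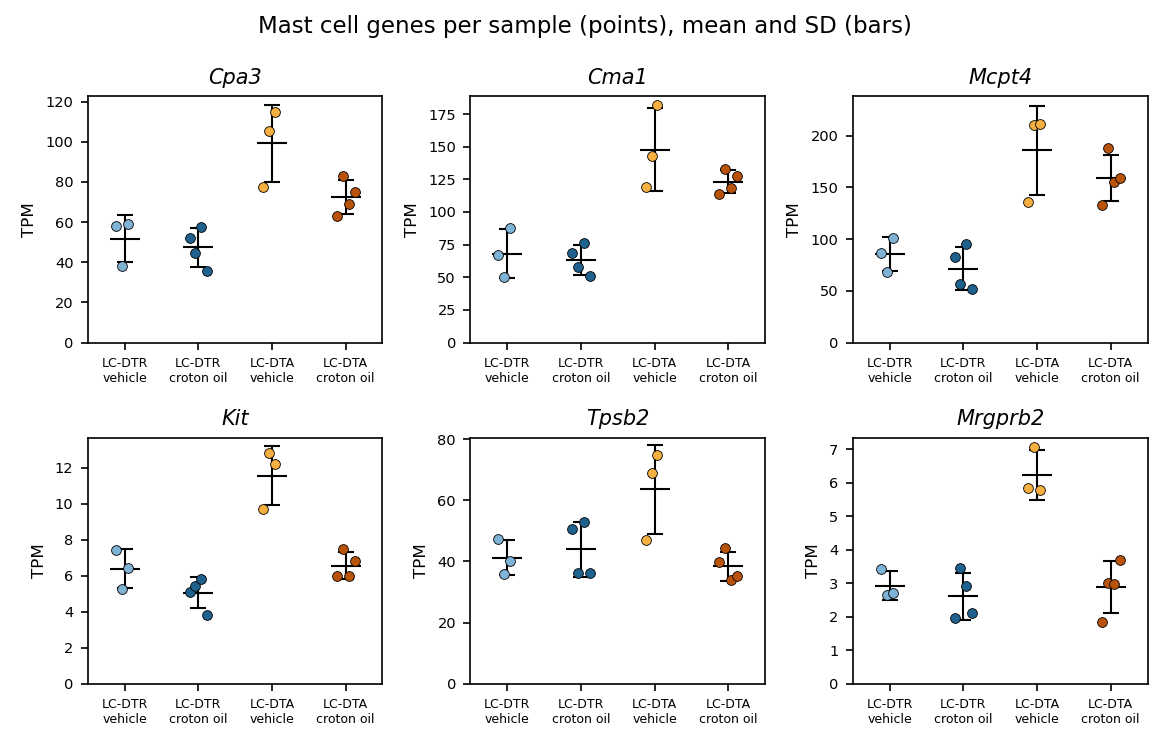
Expression in TPM (vertical axes, starting at 0) of 6 mast cell genes in each of the 14 samples (points), with mean and SD (bars), for the 4 groups of genotype and treatment. Cpa3 measured 51.7 ± 11.6 TPM in LC-DTR vehicle, 47.5 ± 9.65 in LC-DTR croton oil, 99.2 ± 19.2 in LC-DTA vehicle and 72.5 ± 8.52 in LC-DTA croton oil samples.

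All 12 fibroblast and extracellular matrix genes were higher in LC-DTA under vehicle, also when adjusted over the list alone (12), with fibrillin Fbn1 at 1.20 ± 0.19, dermatopontin Dpt at 1.01 ± 0.20 and the collagen gene Col1a1 at 1.73 ± 0.35. The median was 0.93 relative to the median gene. Camera gave the fibroblast list adjusted p = 3.93e-05, and adjusted p = 0.721 with an estimated correlation. Of 16 macrophage and monocyte genes 11 were higher (11 adjusted over the list alone), with the receptor Csf1r at 1.20 ± 0.18 and Cd68 at 0.87 ± 0.14. Their relative median was 0.71. Camera gave the macrophage and monocyte list adjusted p = 0.00188, and adjusted p = 0.721 with an estimated correlation. Of 10 endothelial identity genes 4 were higher (5 adjusted over the list alone), with Egfl7 at 1.48 ± 0.12 and VE-cadherin Cdh5 at 1.03 ± 0.12. Camera gave the endothelial identity list adjusted p = 0.00511, and adjusted p = 0.721 with an estimated correlation. Of 11 endothelial activation genes 7 were higher (9 higher and 1 lower adjusted over the list alone), with Angpt2 at 1.29 ± 0.17 and Apln at 1.69 ± 0.24. The relative medians of these endothelial lists were 0.26 and 0.66, and camera gave the second adjusted p = 0.00804, and adjusted p = 0.721 with an estimated correlation.

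Of 19 phorbol ester and AP-1 targets 11 were higher and 1, the transglutaminase Tgm1, was lower in LC-DTA under vehicle (14 and 2 adjusted over the list alone), with Mmp3 and Plaur, at 1.498 ± 0.19, as examples. The relative median was 0.72. Camera gave the phorbol ester and AP-1 list adjusted p = 0.00295, and adjusted p = 0.721 with an estimated correlation. Of 13 cartilage genes 7 were higher (7 adjusted over the list alone), with Col11a2 at 0.94 ± 0.15 and Sox9 at 0.63 ± 0.11. Their relative median was 0.53. Camera gave the cartilage list adjusted p = 0.0207, and adjusted p = 0.721 with an estimated correlation. Of 11 Langerhans cell and antigen presentation genes 7 were higher (8 adjusted over the list alone), with the costimulatory gene Cd86 at 1.02 ± 0.23 and H2-DMb1, a chaperone of MHC class II, at 0.84 ± 0.19; both are expressed by many antigen-presenting cells. The relative median was 0.74. Camera gave the antigen presentation list adjusted p = 0.0278, and adjusted p = 0.779 with an estimated correlation. Of 13 Schwann cell and nerve genes 8 were higher and 1, the neurotrophin receptor Ngfr, was lower (10 and 1 adjusted over the list alone), with the myelin genes Pmp22 at 0.74 ± 0.13 and Mbp at 0.57 ± 0.11. Their relative median was 0.57. Camera gave the Schwann cell list adjusted p = 0.0483, and adjusted p = 0.779 with an estimated correlation.

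Of 17 genes of basal and differentiated epidermis 5 were lower and 1, the integrin Itgb4, was higher in LC-DTA under vehicle (6 and 1 adjusted over the list alone), with Krtdap at -0.53 ± 0.082 and the cornification protease Casp14 at -0.94 ± 0.16. The median was -0.48 relative to the median gene. Camera gave the epidermal list adjusted p = 3.94e-06, and adjusted p = 0.0868 with an estimated correlation, and both the list and Krtdap lost their calls under quantile normalization. In the keratinocyte stress list 5 of 23 genes were lower, as many as when adjusted over the list alone, among them the interleukin-36 genes Il1f9 at -0.81 ± 0.12 and Il1f8 at -1.002 ± 0.15. Camera called that list lower (adjusted p = 0.0229, and adjusted p = 0.779 with an estimated correlation) although its median was 0.19 and its mean -0.033, so median and test differed in sign. Of 13 T cell genes 1 was higher, Cd4 at 1.32 ± 0.21, and 1 was lower, Cd3g at -0.51 ± 0.15, the same counts when adjusted over the list alone. Camera gave the T cell list adjusted p = 0.0439, and adjusted p = 0.779 with an estimated correlation. Of 14 sebaceous gland genes 2 were lower (1 adjusted over the list alone), with Awat2 as the example. Camera gave the sebaceous gland list adjusted p = 0.0483, and adjusted p = 0.779 with an estimated correlation.

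In this comparison the lists with the highest adjusted p depended on single samples. Without LC-DTR vehicle sample 2 and without LC-DTA vehicle sample 2 the camera calls of the keratinocyte stress, T cell, sebaceous gland, antigen presentation and Schwann cell lists were lost. The keratinocyte stress, T cell and sebaceous gland calls were also lost after both rescalings and by fry, and these and the Schwann cell call with a filter of 5 TPM. With only the compared groups in the fit the keratinocyte stress, T cell and Schwann cell calls were lost. The Schwann cell call was further lost without LC-DTR vehicle sample 3, LC-DTA vehicle sample 3, LC-DTR croton oil sample 2, or LC-DTA croton oil sample 2, 3 or both 3 and 4, and with pseudocount 0.1. The T cell call was lost without LC-DTA vehicle sample 3, and the sebaceous gland call without LC-DTR croton oil sample 2, with either other pseudocount and without the filter. Over these alternatives the adjusted p was 0.0567 to 0.599 for the T cell, 0.0512 to 0.599 for the keratinocyte stress, 0.0527 to 0.599 for the sebaceous gland, 0.0651 to 0.0706 for the antigen presentation and 0.0514 to 0.116 for the Schwann cell list. Cd3g lost its call, at log2 values from -0.51 to -0.43, without LC-DTR vehicle sample 1 or 2 or LC-DTA vehicle sample 2 or 3 and with only the compared groups in the fit.

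The fourth comparison set the genotypes against each other after croton oil. Genes of the cell cycle, of monocytes and macrophages, of mast cells, of the interferon response and of the extracellular matrix were higher in LC-DTA ears, and genes that glucocorticoids induce were lower. Ccl24, a chemokine for eosinophils (chromosome 5, 135569937 to 135573049), measured 47.2 ± 15.03 TPM in LC-DTA and 3.68 ± 0.922 TPM in LC-DTR. Fkbp5 (chromosome 17, 28399094 to 28517527) measured 54.6 ± 10.5 TPM in LC-DTA and 346 ± 17.5 TPM in LC-DTR, and Mcm2 measured 17.9 ± 1.57 and 4.60 ± 0.639 TPM.

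After croton oil limma called 7688 genes between the genotypes, 5041 higher and 2647 lower in LC-DTA, and of these 503 were higher and 215 lower by at least 2-fold. The share called higher was 65.6% as deposited, 52.0% after median ratio scaling (3876 higher and 3585 lower) and 50.1% after quantile normalization (3740 higher and 3730 lower). The increases with the largest log2 values were those of Ccl24 at 3.32 ± 0.27, the monocyte gene Ly6c2 at 3.14 ± 0.32, Sptssb at 3.09 ± 0.43, the hyaluronan synthase Has3 at 3.07 ± 0.32, Serpina3b at 3.03 ± 0.33 and Plac8 at 2.99 ± 0.44, with limma adjusted p between 2.04e-06 and 1.06e-04. Among the large decreases were those of Best2 at -3.20 ± 0.32, the transcription factor Zbtb16 (chromosome 9, 48654297 to 48836222) at -3.01 ± 0.27, Serpina3m at -2.996 ± 0.17, Trp53inp1 at -2.75 ± 0.18, Tsc22d3, a glucocorticoid-induced leucine zipper, at -2.75 ± 0.28 and Fkbp5 at -2.66 ± 0.21. Their limma adjusted p lay between 2.13e-07 and 7.73e-06.

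Of 16 circadian and glucocorticoid genes 11 were lower in LC-DTA after croton oil and none was higher, the same counts when adjusted over the list alone, with Fkbp5, Zbtb16 and Tsc22d3 as above and the clock gene Per1 at -1.43 ± 0.16. Camera gave the circadian and glucocorticoid list adjusted p = 1.37e-07, and adjusted p = 0.463 with an estimated correlation. Of 15 cell cycle genes 14 were higher (14 adjusted over the list alone), with Mcm2 at 1.76 ± 0.10, Mcm5 at 1.89 ± 0.13, Top2a at 1.58 ± 0.17 and Cdk1 at 1.62 ± 0.19. Camera gave the cell cycle list adjusted p = 4.11e-06, and adjusted p = 0.848 with an estimated correlation. Of 16 macrophage and monocyte genes 12 were higher (12 adjusted over the list alone), with the chemokine receptor Ccr2 at 2.41 ± 0.17, lysozyme Lyz2 at 1.91 ± 0.14 and Ly6c2 as examples. Camera gave the macrophage and monocyte list adjusted p = 0.00743, and adjusted p = 0.883 with an estimated correlation. Of 16 interferon response genes 12 were higher (15 adjusted over the list alone), with Oas2 at 1.38 ± 0.18 and Oas1a at 1.31 ± 0.18. Camera gave the interferon response list adjusted p = 0.00743, and adjusted p = 0.883 with an estimated correlation, and the camera call was lost, at adjusted p = 0.293, with a filter of 5 TPM. Of 12 fibroblast and extracellular matrix genes 11 were higher (11 adjusted over the list alone), with Fbn1 at 1.46 ± 0.16 and lumican Lum at 1.24 ± 0.20. Camera gave the fibroblast list adjusted p = 0.00743, and adjusted p = 0.883 with an estimated correlation. Tsc22d3 measured 301 ± 115 TPM in LC-DTR vehicle, 303 ± 105 in LC-DTR croton oil, 148 ± 51.4 in LC-DTA vehicle and 42.7 ± 6.86 in LC-DTA croton oil samples. It was not called after croton oil in LC-DTR, at 0.020 ± 0.30, and was lower in LC-DTA already under vehicle, at -0.997 ± 0.32 (limma adjusted p = 0.0362). That vehicle call was lost, at -0.997 to -0.73 and adjusted p from 0.0512 to 0.168, without LC-DTR vehicle sample 1 or 2, LC-DTA vehicle sample 1 or 3, or LC-DTA croton oil samples 3 and 4, without the filter and with only the compared groups in the fit.

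Of 20 mast cell genes 14 were higher in LC-DTA after croton oil and 6 were not called (14 higher adjusted over the list alone). Camera gave the mast cell list adjusted p = 0.0149, and adjusted p = 0.883 with an estimated correlation. Mrgprb1 was higher by 1.52 ± 0.17, Mcpt4 by 1.17 ± 0.20, Cma1 by 0.96 ± 0.17 and Cpa3 by 0.62 ± 0.17, with limma adjusted p between 1.28e-05 and 0.00794. Kit was higher by 0.33 ± 0.13 (limma adjusted p = 0.0441), a call lost, at log2 values from 0.13 to 0.36, after both rescalings, with pseudocount 5, without the filter, without LC-DTR croton oil sample 1 or 4, without LC-DTA croton oil sample 2 or 4, without LC-DTA vehicle sample 3 and without LC-DTA croton oil samples 3 and 4. Tpsb2 differed by -0.18 ± 0.16 and Mrgprb2 by 0.11 ± 0.16, and neither was called (limma adjusted p = 0.373 and 0.599). Of the basophil and eosinophil genes Ccr3 was higher by 0.92 ± 0.093, Cd200r3 by 1.04 ± 0.11 and Mcpt8 by 0.89 ± 0.14. No LC-DTR sample reached 1 TPM of any of the 8 listed genes, so that these 3 passed the filter through LC-DTA samples alone. Their camera call (adjusted p = 0.0182, and adjusted p = 0.463 with an estimated correlation) was lost without the filter, where the same genes and Siglec5 were higher (4 of 8, also adjusted over the list alone) at camera adjusted p = 0.0633, and adjusted p = 0.75 with an estimated correlation; it was lost with pseudocount 5 too, at adjusted p = 0.0620. Of 15 immediate early genes 4 were lower and none was higher (3 lower adjusted over the list alone), with Btg2 at -0.86 ± 0.10, Klf4 at -0.62 ± 0.083 and Jun at -0.89 ± 0.24. Camera gave the immediate early list adjusted p = 0.0149, and adjusted p = 0.883 with an estimated correlation, and the camera call was lost under quantile normalization and by fry, at adjusted p of 0.0988 and 0.111.

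**Figure D4:**
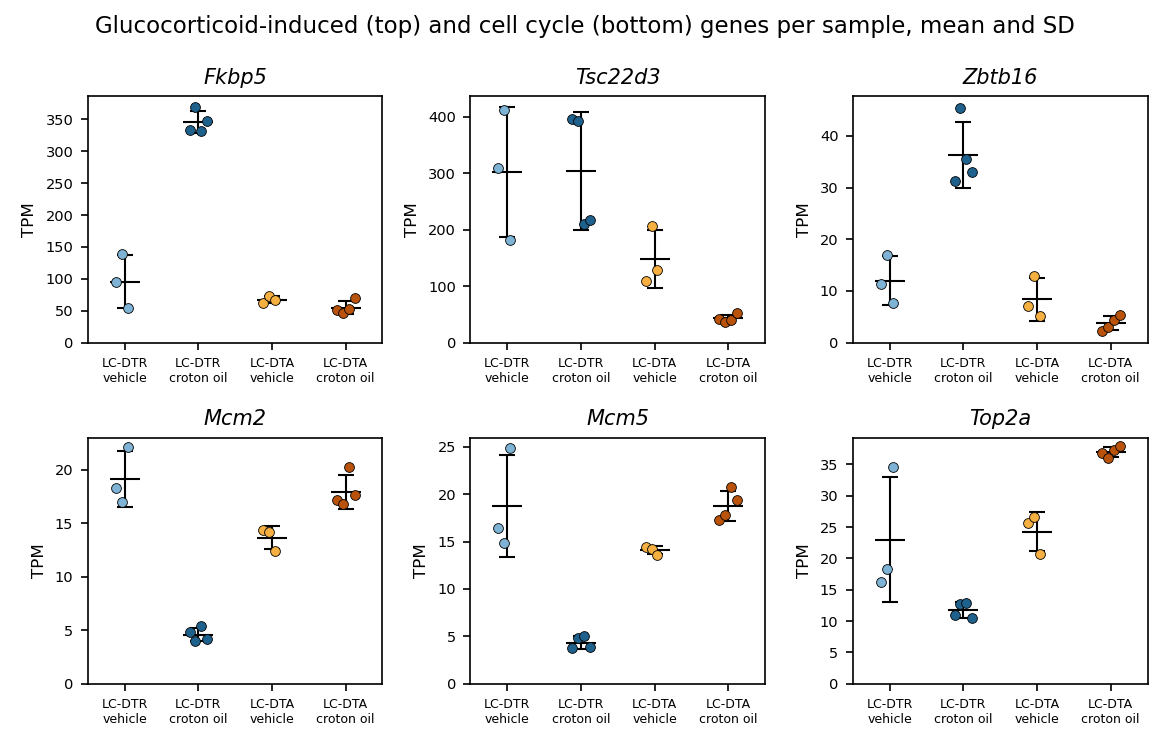
Expression in TPM (vertical axes, starting at 0) of 3 genes that glucocorticoids induce (upper panels) and 3 cell cycle genes (lower panels) in each of the 14 samples (points), with mean and SD (bars), for the 4 groups of genotype and treatment. Fkbp5 measured 346 ± 17.5 TPM and Mcm2 4.60 ± 0.639 TPM in LC-DTR croton oil samples, against 54.6 ± 10.5 and 17.9 ± 1.57 TPM in LC-DTA croton oil samples.

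The fifth comparison tested whether the response to croton oil differed between the genotypes, as the response in LC-DTA minus that in LC-DTR. Cell cycle genes fell in LC-DTR and not in LC-DTA. The glucocorticoid-induced gene Fkbp5 went from 95.8 ± 41.8 to 346 ± 17.5 TPM in LC-DTR and from 67.03 ± 5.48 to 54.6 ± 10.5 TPM in LC-DTA. The monocyte receptor gene Ccr2 rose in LC-DTA, from 5.74 ± 0.677 to 37.9 ± 5.31 TPM, against 7.25 ± 1.65 and 6.44 ± 1.72 TPM in LC-DTR. The difference of responses itself was tested for each gene named here. Serpina3c (chromosome 12, 104146382 to 104153870) went from 8.07 ± 1.14 to 34.4 ± 3.94 TPM in LC-DTR and from 10.6 ± 1.24 to 6.93 ± 0.653 TPM in LC-DTA.

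Limma called 3389 genes for the difference of responses, 1541 with a more positive and 1848 with a more negative response in LC-DTA. The count was 2214 without LC-DTA vehicle sample 2. Those with the lowest p were, on the positive side, Mcm2 at 2.22 ± 0.15, the helicase Hells at 2.20 ± 0.19, Mcm5 at 2.25 ± 0.20, Ccr2 at 2.68 ± 0.25 and the pocket protein Rbl1 at 1.56 ± 0.15, with limma adjusted p between 8.28e-06 and 9.33e-05. On the negative side they were Serpina3c at -2.51 ± 0.16, Angptl7 at -1.99 ± 0.16, the glutathione peroxidase Gpx3 at -1.55 ± 0.14, Wnt11 at -1.76 ± 0.16 and the retinal dehydrogenase Aldh1a1 at -1.80 ± 0.16, with limma adjusted p between 5.37e-06 and 6.03e-05. Serpina3c has close copies that could share its reads.

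Of 15 cell cycle genes 12 had a more positive response in LC-DTA (14 adjusted over the list alone), with Top2a at 1.43 ± 0.26 and Tyms at 1.03 ± 0.20 beside the genes above. Camera gave the cell cycle list adjusted p = 7.95e-09, and adjusted p = 0.407 with an estimated correlation. Of 16 circadian and glucocorticoid genes 11 had a more negative response (11 adjusted over the list alone), with the clock activator Arntl at -0.98 ± 0.13, Fkbp5 at -2.24 ± 0.31, Nr1d1 at -1.19 ± 0.19 and Zbtb16 at -2.51 ± 0.42. Camera gave the circadian and glucocorticoid list adjusted p = 1.79e-05, and adjusted p = 0.407 with an estimated correlation. The basophil and eosinophil genes Ccr3 at 0.81 ± 0.14, Mcpt8 at 0.88 ± 0.22 and Cd200r3 at 0.61 ± 0.17 had a more positive response, and had passed the filter through LC-DTA samples alone. For these 3 genes camera gave adjusted p = 0.0144, and adjusted p = 0.407 with an estimated correlation. Without the filter the same genes of the 8 listed were called (3 adjusted over the list alone), and camera gave adjusted p = 0.0319, and adjusted p = 0.383 with an estimated correlation. The call of Cd200r3 was lost, at 0.48 to 0.85, without LC-DTA vehicle sample 2, with pseudocount 0.1 and without LC-DTA croton oil samples 3 and 4. Of 10 endothelial identity genes 4 had a more negative response (7 adjusted over the list alone), with Emcn at -0.74 ± 0.12, Cdh5 at -0.73 ± 0.15 and Egfl7 at -0.75 ± 0.16. Camera gave the endothelial identity list adjusted p = 0.0218, and adjusted p = 0.828 with an estimated correlation, and the camera call was lost, at adjusted p of 0.0527 and 0.0542, without LC-DTR vehicle sample 2 and without LC-DTA croton oil samples 3 and 4. Of 17 epidermal genes 6 had a more positive and 1, loricrin Lor, a more negative response, the same counts when adjusted over the list alone, with the basal keratins Krt14 at 0.76 ± 0.14 and Krt5 at 0.79 ± 0.19. Camera gave the epidermal list adjusted p = 0.0341, and adjusted p = 0.407 with an estimated correlation. That call was lost, at adjusted p from 0.0542 to 0.260, under quantile normalization, without LC-DTA croton oil sample 1 or 3, LC-DTR croton oil sample 2 or LC-DTR vehicle sample 2, and without LC-DTA croton oil samples 3 and 4.

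The mast cell list was not called for the difference of responses (1 of 20 genes, Rab27b, more positive and 4 more negative, the same counts when adjusted over the list alone). Camera gave the mast cell list adjusted p = 0.798, and adjusted p = 0.969 with an estimated correlation. Rab27b, a regulator of granule release, had 0.52 ± 0.12, Hdc -1.20 ± 0.29, Mrgprb2 -0.78 ± 0.24 and Tpsb2 -0.77 ± 0.24, with limma adjusted p between 0.00788 and 0.0358. The calls of Mrgprb2 and Tpsb2 were lost without any 1 of LC-DTR vehicle samples 2 and 3, LC-DTA vehicle samples 2 and 3 and LC-DTR croton oil sample 3, and without the filter. That of Mrgprb2 was also lost without LC-DTR croton oil sample 2 or LC-DTA vehicle sample 1 and with pseudocount 0.1, at log2 values from -0.93 to -0.67 over all these alternatives. That of Tpsb2 was also lost without LC-DTR croton oil sample 1 or LC-DTA croton oil sample 3, 4 or both, at -0.77 to -0.64. Cpa3 at -0.32 ± 0.26, Cma1 at -0.16 ± 0.25, Mcpt4 at 0.071 ± 0.31 and Kit at -0.44 ± 0.20 were not called, with limma adjusted p between 0.118 and 0.891. Kit was called, at -0.54, without LC-DTR croton oil sample 4 and, at -0.48, under quantile normalization.

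Across the 14693 genes tested, the log2 responses of the genotypes to croton oil had a Pearson r of 0.69 and a Spearman rho of 0.61, and the slope of the LC-DTA response on the LC-DTR response was 0.76; genes are not independent replicates, so no p is given. The responses shared no control libraries. Limma called 2120 genes higher in both genotypes, where independent lists of these sizes would share 784, and 2604 lower in both, where independent lists would share 1495. The calls were opposite for 386 genes. Of 11086 genes called in either genotype, 3337 were also called for the difference of responses. The differences between the genotypes under vehicle and after croton oil, which also shared no library, had a Pearson r of 0.44 and a Spearman rho of 0.36, with 1496 genes higher in LC-DTA in both (964 for independent lists), 469 lower in both (141) and 273 opposite.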

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

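The tests of the dermis share, of adipocytes and sebaceous cells and of epidermal genes against cell cycle genes were chosen only after the result was seen. The bootstrap intervals in this part resample genes, which are not independent replicates, and do not measure the spread between samples. Chance sets a sample apart in about 1 in 20 groups, and 6 of 202 groups of 4 samples held such a sample. Angptl7 was 933 TPM in LC-DTR croton oil sample 2 against 687 to 713 in the others of its group, and Klf4 was 1002 against 802 to 829 in the same sample. LC-DTR croton oil sample 3 had 2.49 TPM of Cyp2w1 against 1.72 to 1.81 and 7.74 TPM of Sostdc1 against 3.43 to 3.95. BC100530 was 136 TPM in LC-DTA croton oil sample 4 against 230.1 to 241 in the others. The number of genes at 1 TPM or more was 13753 in LC-DTR croton oil sample 4 against 13888 to 13913. A row named as a date, which names no gene, had 3.49 ± 0.292 TPM in LC-DTA croton oil and 1.60 ± 0.271 TPM in LC-DTA vehicle samples.

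The response to croton oil, LC-DTA minus LC-DTR, differed for 3389 of 14693 genes by limma, and among 103 named genes it differed for 54. Some of the named genes were chosen by their low p in this same test, so these shares cannot be compared. Among genes of the cell cycle and DNA replication the log2 differences were 2.22 for Mcm2, 2.25 for Mcm5, 2.20 for Hells, 1.56 for Rbl1, 1.43 for Top2a, 1.35 for Mki67, 1.03 for Tyms and 0.51 for Pcna. Among genes of the clock and of the glucocorticoid response they were -2.51 for Zbtb16, -2.24 for Fkbp5, -1.19 for Nr1d1 and -0.98 for Arntl. Other genes with a more positive response in LC-DTA were BC100530 at 3.64, Stfa1 at 3.06, Stfa3 at 2.87, Ccr2 at 2.68, Ly6c2 at 2.58, Cxcl5 at 2.33, Ch25h at 1.59, Cd177 at 1.40, Il33 at 1.20, Il6 at 1.035, Gzmb at 1.03, Mcpt8 at 0.88, Ccr3 at 0.81, Osm at 0.73, Cd200r3 at 0.61 and Rab27b at 0.52. Positive too were Pla2g4a at 0.80, Krt5 at 0.79 and Krt14 at 0.76. More negative were Serpina3c at -2.51, Angptl7 at -1.99, Aldh1a1 at -1.80, Wnt11 at -1.76, Gpx3 at -1.55, Calca at -1.27, Hdc at -1.20, Rfx2 at -1.19, Sele at -1.08, Grik5 at -0.86, Plaur at -0.83, Mrgprb2 at -0.78, Tpsb2 at -0.77, Egfl7 at -0.75, Emcn at -0.74, Cdh5 at -0.73, Klf4 at -0.70, Msx2 at -0.68, Bag3 at -0.63, Dusp5 at -0.61, Btg2 at -0.57, Crlf2 at -0.48 and Dnajb1 at -0.29. The lists called for the difference of responses had medians of 1.14 for the cell cycle, 0.81 for the 3 of 8 basophil and eosinophil genes that passed the filter, 0.25 for the epidermis, -0.48 for endothelial identity and -0.92 for the clock and glucocorticoid genes.

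The first pattern was the higher level of mast cell genes in LC-DTA under vehicle. The scaling of the TPM is argued against by 12 of the 13 called genes that stayed called higher after median ratio scaling. A larger share of dermis would raise the genes of all non-epidermal cells alike and stays open: the median of the 20 mast cell genes lay 0.224 above that of 96 genes of other non-epidermal lists with fibroblasts and macrophages included (95% bootstrap interval over genes from -0.0414 to 0.533), 0.454 above that of the 68 genes without these lists (0.149 to 0.654) and -0.242 from that of 12 fibroblast genes (-0.715 to -0.00773). DT treatment and the range of the numbers in the labels cannot be told apart from genotype. A difference in the number or the content of mast cells may be put beside these as a biological hypothesis, which the values neither exclude nor single out.

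The second pattern was the lower level of glucocorticoid-induced genes in LC-DTA after croton oil, of which Tsc22d3 was called lower under vehicle too. Fewer adipocytes or sebaceous cells would lower the genes of those cells. Their 26 genes had a median of 0.179 (interval over genes -0.227 to 0.260). For these genes this argues against it, without a measure of the spread between samples. A different hour of sampling stays open: 7 clock output genes had a median of -0.558 (-0.868 to -0.153) and 4 of them were lower, but Arntl and Npas2, which would move the other way, were lower too, at -0.61 and -1.13. In a second list of glucocorticoid-induced genes, named before its values were seen, 11 of 12 were lower with a median of -0.822 (-1.21 to -0.434; camera p = 7.15e-08, and p = 0.0321 with an estimated correlation). This goes with the hypothesis of lower glucocorticoid receptor activity in LC-DTA ears, or of higher activity in LC-DTR ears, after croton oil. The second list was compared only between the genotypes, so it cannot tell these apart. Fkbp5 rose after croton oil in LC-DTR, while Tsc22d3 was not called there. Zbtb16 was 7.58 to 17.0 TPM in LC-DTR vehicle and 31.4 to 45.5 TPM in LC-DTR croton oil samples. In LC-DTA, vehicle and croton oil samples had 5.11 to 13.0 and 2.31 to 5.34 TPM of Zbtb16. They had 110 to 206 and 37.2 to 52.6 TPM of Tsc22d3, and 61.5 to 72.4 and 45.9 to 69.9 TPM of Fkbp5. Among these genes a rise in LC-DTR and a fall in LC-DTA thus both occurred. Either reading may come with DT treatment or with differences between the sets of samples as well as with genotype, and these were not tested.

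The third pattern was the fall of cell cycle genes after croton oil in LC-DTR and not in LC-DTA. Dilution of epidermal RNA by other cells would lower epidermal genes as much. The median of 15 cell cycle genes lay -0.692 (-1.31 to -0.264) from that of the 17 genes of the epidermal list. From that of 6 basal keratinocyte genes it lay -1.03 (-1.65 to -0.190). For these genes this argues against dilution as the whole cause, without a measure of the spread between samples. It stays open as part of the cause, since 9 of the 17 epidermal genes fell and 2 rose, with a median of -0.36 (-0.787 to 0.0638). Whether dividing cells that entered LC-DTA ears offset a fall there was not tested and stays open. A halt of the cell cycle in LC-DTR ears may be put forward as a hypothesis, and a link to glucocorticoid-induced genes was not tested. DT treatment and differences between the sets of samples may contribute and were not tested.

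Other splits of the samples were fitted for each count of called genes. In LC-DTR 1 of 35 splits, the real one, gave as many as 7577 genes and the highest other gave 5374. In LC-DTA 1 of 35 gave 8619 and the highest other 5456. Both shares were under 0.05, and 1 of 35 is the lowest share that 35 splits can give. For the genotypes after croton oil 1 of 35 splits gave 7688 and the highest other 0, again the lowest share possible. A low share speaks against a random grouping of these samples. It does not tell treatment or genotype apart from other differences between the same groups. Under vehicle the 10 splits are too few for a share under 0.05, with 3595 genes in the real split and 1 in the highest other. For the difference of responses 3 of 100 splits, the real one included, gave at least the real 3389 genes. That share is under 0.05 too, but it cannot exclude chance, because splits also mixed the genotypes of the croton oil samples. Such splits put the genotype difference into the spread and gave at most 88 genes. Splits that kept or exchanged the croton oil groups whole gave from 1638 to 7456 genes, with the real count inside this range. The highest other, 7456, kept the labels of all 6 vehicle samples and exchanged the genotype of all 8 croton oil samples, which puts the genotype difference itself into the fit, and so points to the structure of the samples. The other one above the real count, 5263, kept the labels of all 8 croton oil samples and of 2 of the 6 vehicle samples.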

How the results depend on the processing

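The alternatives were all planned, and no test in this part was chosen only after the result was seen. Of 232 results for named genes, the direction and the side of the threshold stayed the same for 232 without the trend and with robust estimation, 231 with pseudocount 5, 229 with pseudocount 0.1 and after median ratio scaling, 227 without the filter and under quantile normalization, 214 of 214 with a filter of 5 TPM, 194 of 198 with only the compared groups in the fit, 217 of 224 without LC-DTA croton oil samples 3 and 4, and 223 to 232 of 226 or 232 when 1 sample was left out. Of 49 list calls, 49 stayed without the trend and with robust estimation, 47 with pseudocount 0.1 and without the filter, 46 with pseudocount 5, 45 after median ratio scaling, 42 under quantile normalization, 39 of 46 with a filter of 5 TPM, 40 of 44 with only the compared groups and 42 of 46 without the 2 LC-DTA samples. Where fewer results are given, the gene or list no longer passed the filter or, for the difference of responses, all groups were needed, so that no fit with only the compared groups could be made. The basophil and eosinophil list had too few measured genes for a test with the filter of 5 TPM and without LC-DTA croton oil sample 2, 3 or 4, or 3 and 4 together. The unknown depth limits genes of low TPM most.

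Camera with an estimated correlation called 0 lists in each of the 5 comparisons, where the preset correlation gave 12, 11, 13, 8 and 5; the lowest adjusted p was 0.290, 0.274, 0.0868, 0.463 and 0.407. With the estimated correlation a list needs to differ by more to be called. Fry called 19 lists for croton oil in LC-DTA and 15 for the genotypes after croton oil. For Cd207 the log2 difference in LC-DTR was 0.74 ± 0.23 at pseudocount 1 without the filter, 1.76 at pseudocount 0.1 and 0.23 at pseudocount 5, since its TPM lie near the pseudocounts. Mrgprb2 in LC-DTA against LC-DTR under croton oil, not called at 0.11, reversed to -0.077 under quantile normalization and to -0.070 without LC-DTA croton oil samples 3 and 4; the cause was not tested.

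When 1 sample was left out, the counts ranged from 6419 to 7702 for croton oil in LC-DTR, 7216 to 8916 for croton oil in LC-DTA, 6560 to 7915 for the genotypes after croton oil, 1781 (without LC-DTR vehicle sample 2; 2093 without LC-DTA vehicle sample 3) to 3777 for the genotypes under vehicle and 2214 (without LC-DTA vehicle sample 2) to 3569 for the difference of responses. At the lowest counts of these last comparisons, 1766 and 2180 of the genes called with all samples were still called. The lists called ranged from 8 (without LC-DTR vehicle sample 2) to 15 under vehicle and, for the difference of responses, from 3 (without LC-DTA croton oil sample 3) to 8 (without sample 1 of LC-DTR vehicle or LC-DTR croton oil, or sample 3 of LC-DTA vehicle). Uncalled mast cell genes changed sign: in LC-DTR Cpa3 ranged from -0.32 to 0.012 (above 0 without LC-DTR croton oil sample 4), Cma1 from -0.28 to 0.11 (above 0 without that sample or LC-DTR vehicle sample 3) and Tpsb2 from -0.017 to 0.18 (below 0 without LC-DTR vehicle sample 2 or LC-DTR croton oil sample 3). For the difference of responses Cma1 ranged from -0.35 to 0.038 (above 0 without LC-DTR vehicle sample 2 or LC-DTA vehicle sample 3) and Mcpt4 from -0.14 to 0.22 (below 0 without LC-DTR vehicle sample 3, LC-DTR croton oil sample 2 or 4, LC-DTA vehicle sample 1 or LC-DTA croton oil sample 2). The cause was not tested. The correlation of the responses across genes ranged from 0.644 to 0.711.

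With the replicate block, limma called 6445, 7733, 2879, 7048 and 2660 genes in the 5 comparisons, and 227 of 232 gene results and 48 of 49 list calls stayed the same. The calls that ended were those of Tpsb2 and Cd3g under vehicle, Kit after croton oil, Mrgprb2 and Tpsb2 for the difference of responses and the Schwann cell and nerve list under vehicle. The replicate numbers do not pair the samples: deviations from the group means of samples with the same number had a mean correlation of -0.0785 over 19 pairs (-0.315 to 0.126), against 0.0276 over 54 other pairs, and 0 of 14 samples correlated best with their own number.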

Other observations

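No test in this part was chosen only after the result was seen. Of the sensory neuron list 6 of 18 genes were measured, and Calca, which encodes the precursor of the neuropeptide CGRP, rose after croton oil from 0.0547 ± 0.0475 to 7.42 ± 3.86 TPM in LC-DTR and from 0.191 ± 0.0748 to 2.72 ± 0.713 TPM in LC-DTA, by 2.90 ± 0.24 and 1.63 ± 0.24 on the log2 scale (limma adjusted p = 1.97e-06 and 8.56e-05). The response was smaller in LC-DTA, by -1.27 ± 0.35 (limma adjusted p = 0.0184). Calca was near the lower end of the scale under vehicle and passed the filter through croton oil samples alone. The cell bodies of sensory neurons lie outside the ear, and which cells expressed Calca was not tested. Tac1, the precursor of substance P, also rose, by 0.70 ± 0.18 and 0.77 ± 0.18, while Lpar3 fell, at -0.64 ± 0.12 in LC-DTR and -0.30 ± 0.12 in LC-DTA. In each genotype 2 genes of the list rose and 2 fell, the same counts when adjusted over the list alone. Camera gave the sensory neuron list adjusted p = 0.649 in LC-DTR and 0.667 in LC-DTA, and adjusted p = 0.900 and 0.797 with an estimated correlation. Gzmb, a granzyme of cytotoxic lymphocytes, moved against the direction camera gave the T cell list it belongs to and rose from 1.02 ± 0.513 to 10.1 ± 2.96 TPM in LC-DTR and from 0.931 ± 0.181 to 20.8 ± 3.97 TPM in LC-DTA, with a difference of responses of 1.03 ± 0.29 (limma adjusted p = 0.0226). That last call was lost, at 0.83 to 1.10, without LC-DTR vehicle sample 3, LC-DTA vehicle sample 2 or LC-DTA croton oil samples 3 and 4 and with pseudocount 0.1. Of 13 T cell genes 2 rose and 4 fell in LC-DTR (2 and 5 adjusted over the list alone), and 1 rose and 4 fell in LC-DTA (1 and 3 adjusted over the list alone), with medians of -0.094 and -0.22 and means of 0.077 and 0.052, which differ in sign from the medians. Camera did not call the T cell list, at adjusted p = 0.975 and 0.775, and adjusted p = 0.988 and 0.928 with an estimated correlation.

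Genes of eicosanoid synthesis went both ways. Ptges, a synthase of prostaglandin E, rose by 1.47 ± 0.19 in LC-DTR and 2.04 ± 0.19 in LC-DTA, and Pla2g4a, the phospholipase that releases arachidonic acid, fell from 55.1 ± 2.31 to 31.6 ± 3.65 TPM in LC-DTR and measured 53.04 ± 4.68 and 53.7 ± 5.16 TPM in LC-DTA. The difference of these responses was 0.80 ± 0.13 (limma adjusted p = 0.00158). In LC-DTR 4 of 14 genes rose and 3 fell (3 and 2 adjusted over the list alone), and in LC-DTA 5 rose and 2 fell, the same counts when adjusted over the list alone. Camera gave the eicosanoid list adjusted p = 0.667 and 0.104, and adjusted p = 0.906 and 0.307 with an estimated correlation. The kainate receptor gene Grik5 fell in LC-DTA, at -1.05 ± 0.11 (limma adjusted p = 6.80e-06), and 5 of 8 measured glutamate receptor and transporter genes fell there and 1 rose, the same counts when adjusted over the list alone. Camera gave the glutamate list adjusted p = 0.271, and adjusted p = 0.548 with an estimated correlation. The adipocyte, skeletal muscle and melanocyte lists were also called by camera in none of the comparisons.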
